A study of Mus musculus with 6 samples.

How the data were processed

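The authors deposited 1 table of FPKM, fragments scaled to transcript length and to the mapped fragments of the library, with 29955 gene names and 6 columns, 1 per library. The submitters' processing notes name TopHat2 2.0.9, Cufflinks 2.1.1 and the mouse genome build mm9. Annotation, counting options and filters are not stated. Per the labels' protocols, ribosomal RNA was depleted from total RNA and directional libraries were made. The values were used as deposited, on the scale log2(FPKM + 1), and rescaling was tried only as an alternative. Places are given with starts counted from 1, after the listed starts were found to count from 0. No counts or fragment totals are in the table, so no test based on counts was used.

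Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11816 in number. The test was limma 3.58.1 in R 4.3.3 with an additive model of inhibitor (3 levels) and TGF-β (2 levels), moderated without trend or robust options, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 2 residual degrees of freedom before moderation and a prior of 2.87 degrees of freedom. Its residual spread holds noise and any true dependence of the TGF-β response on the inhibitor together. Comparisons of 2 libraries have no p-value, and genes were counted at a difference of at least 1. A response was counted as standing apart where it lay at least 1 above or below both other responses.

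In simulated data of the same size with 200 planted changes, the fit called 60.6% of TGF-β changes of 0.5, 85.7% of those of 1 and 93.9% of those of 2, with 11 of 11616 unchanged genes called. For the miR-31 inhibitor it called 48.5%, 87.3% and 95.7%, with 4 unchanged genes called. The changes were planted only in genes averaging more than 5 FPKM on the log scale, with residual spreads shuffled between genes. The 200 planted changes also eased the adjusted threshold. In the deposited data Angpt2, at 0.78 ± 0.07 (SE of the fit) with the miR-31 inhibitor, had a limma adjusted p of 0.144. The few inhibitor calls therefore do not exclude changes of 0.5 to 1.

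The 30 gene lists, the tests and the rule for named genes were chosen before the data were examined. The lists held 705 symbols, counting a symbol once in each list that holds it, of which 690 were in the table. The 24 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 in 4 contrasts and adjusted over all 96 tests, and camera with an estimated correlation and fry were run beside it. With the estimated correlation, 0 of the 18 calls held. That version of camera also rests on the 2 residual degrees of freedom, so few lists could pass over 96 tests. For the SRF/MRTF list under TGF-β the estimated correlation was 0.011, near the preset 0.01, yet the camera p went from 1.529e-06 to 0.0416. The loss of calls therefore cannot be credited to correlation between genes alone. The fry test gave 8 calls, all for TGF-β, and tests whether a list moves on balance in a single direction without comparing it with other genes. Its test for changes in either direction was read beside it. Median, mean and direction of the camera test differed in sign for the endothelial identity, cholesterol and reported miR-27 target lists under TGF-β. They also differed for the BMP/Id, secreted factor and Notch lists with the miR-31 inhibitor, and for the lymphatic, small RNA, histone and housekeeping lists with the miR-27 inhibitor. Between the inhibitors they differed for the Smad, SRF/MRTF, YAP/TAZ, secreted factor, interferon and p53 lists. None of these lists was called in that contrast. Of the 30 lists, 2 came from the study and are not independent evidence. For comparisons of 2 libraries, the median of a list was set against 10000 random lists matched on expression in 20 bins. Random lists hold unrelated genes, so genes of a list that move together make its rank look more extreme than it is.

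Named genes were the 12 with the largest rise and the 12 with the largest fall under TGF-β among those past the threshold with the same sign in all 3 transfections. For each inhibitor they were the 8 higher and 8 lower genes with the largest smaller-of-2 difference of the same sign in both TGF-β states. For responses that stand apart they were the 8 above and 8 below for miR-31 and the 4 and 4 for miR-27. In each list, examples came from the 4 tested members with the largest change, and every member of the study's lists was named. Names of several genes, short RNAs, histones and unnamed models were skipped outside the lists, because FPKM measures them poorly. Adam12, Mmp2, Kdr, Pecam1, Cdh5, Nrp1, Vim, Tagln, Cnn1, Cyr61, Spp1 and Slc8a1 lie outside this rule and were named after their values were seen. Some deposited names are older or clone names, and several names can share a place in the genome.

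Seed sites were searched as 7-base matches in annotated 3′ UTRs of GENCODE vM21, of which 10478 tested genes had one. Random genes were matched on expression and 3′ UTR length, and each site was ranked among the distinct arrangements of its bases.

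Depth could be compared only between libraries. From the smallest values, with ratios of whole numbers read within 0.01 log2, the libraries had relative depths of 1, 0.894, 0.904, 0.865, 0.860 and 0.818 in the order of the table, and 45.3% to 54.8% of the low values fitted such ratios, so counts could not be recovered. Short RNA names made up 75.2% to 78.2% of the FPKM sums. Rescaling moved the median of all genes by at most 0.03 in any comparison of 2 libraries.

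The alternatives tried were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, moderation with trend and robust options, no inhibitor block, and leaving out each library. Added after the data were seen were leaving out 41 names listed at 0 and leaving out the 53 short RNA names tested. Recounting list members without 1 library was added then too. The 41 names were at 0 in 1 library or more beside at least 1 FPKM in another library of the same TGF-β state. Some genes and 1 gene list of the 30 are not reported here.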

Results

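The deposited table gives the RNA of MS-1 cells, an immortalised endothelial line from mouse pancreatic islets, after transfection with locked nucleic acid inhibitors of microRNAs. A negative-control inhibitor, an inhibitor of miR-31 and an inhibitor of miR-27 were each combined with 72 h with or without 1 ng/ml TGF-β2, per the labels' protocols. TGF-β drives endothelial cells toward a mesenchymal state, and the question addressed was which part of that change depends on these microRNAs. There were 6 libraries, with 1 library per condition and no replicates. The labels do not say whether the transfections were separate cultures, so the p-values measure only the spread between these samples. The table listed 29955 gene names, of which 11816 had a mean of at least 1 FPKM and were tested. Each library listed between 11680 and 11791 genes at 1 FPKM or more.

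The largest rises with TGF-β, in all 3 transfections, included single genes for muscle proteins, an integrin and the matrix. Tnnt2, which encodes the troponin T of heart muscle, rose from 3.11 to 100 FPKM with the negative-control inhibitor, from 2.86 to 102 with the miR-31 inhibitor and from 2.88 to 101 with the miR-27 inhibitor. Dapk2, a kinase linked to cell death and autophagy, rose the most, from 0.0838 to 24.4, 0.193 to 34.4 and 0.125 to 29.8 FPKM in the same order. Itgb5, an integrin subunit that takes part in the activation of latent TGF-β, rose by 4.12 ± 0.07 (SE of the fit, log2 of FPKM + 1, adjusted p = 2.015e-05). The matrix genes Bgn (3.94), Ctgf (3.77) and Col3a1 (3.67) rose with it. Edn1, the precursor of the vasoconstrictor endothelin, rose by 3.93, from 3.05 to 55.2 FPKM with the miR-31 inhibitor. Vwf, a clotting factor stored by endothelial cells, rose by 3.93 as well, from 0.426 to 17.2 FPKM with the negative-control inhibitor. The anion transporter Slco4a1 (3.77), D0H4S114 (3.77), the chemokine gene Ccl17 (3.74) and the protease gene Ctsw (3.67) complete the 12 largest rises.

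The largest fall was that of Nov, which encodes a secreted matricellular protein of the same family as Ctgf. Nov fell by 5.12 ± 0.04 (adjusted p = 4.159e-06), from 89.7 to 1.61, 98.0 to 1.83 and 90.4 to 1.62 FPKM. Angpt2, whose product destabilises vessels through the receptor Tek, fell by 3.41, from 48.9 to 4.08 FPKM with the negative-control inhibitor. The actin regulator Eps8 fell by 4.18, the neurofilament gene Nefl by 3.89, and the laminin receptor subunit Itga6 by 3.23, together with its neighbour BC024571 (3.15). Hmga1 and Il24 fell by 3.23 each, the natriuretic peptide gene Nppb by 2.99 and the junction gene Ppl by 2.84. Of the cysteine protease inhibitors, Stfa3 fell by 4.14, and Stfa2 was listed at 0 in all 3 libraries with TGF-β after 6.56, 7.43 and 6.19 FPKM without it. Their family has near-identical copies, so reads shared between copies limit both values.

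**Figure D1:**
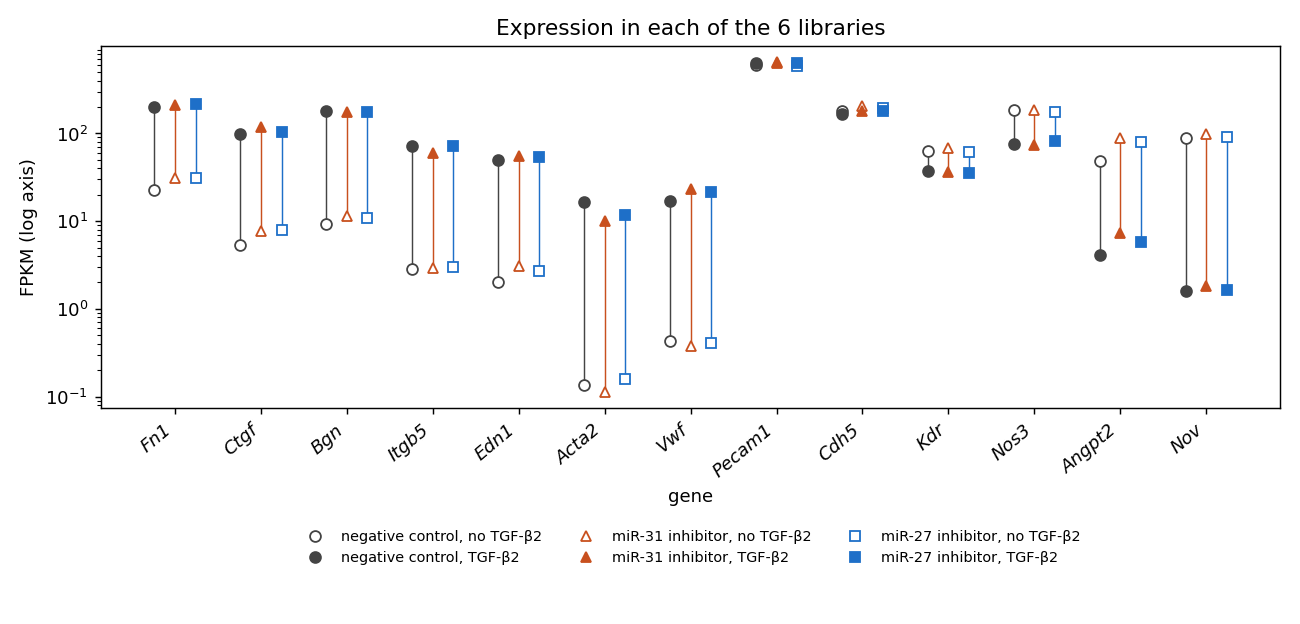
FPKM of 13 genes on a log y axis in each of the 6 libraries, with the genes on the x axis, circles for the negative-control, triangles for the miR-31 and squares for the miR-27 inhibitor, open without and filled with TGF-β, and a line joining both libraries of a transfection. Nov lies between 89.7 and 98.0 FPKM without TGF-β and at or under 1.83 FPKM with it, while Pecam1 lies between 593 and 647 FPKM throughout.

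Of all 11816 genes tested, 50.2% passed for TGF-β, 2677 higher and 3249 lower, and the counts within lists are to be read against that share. Genes for the extracellular matrix rose as a group. Of the 33 tested, 25 rose and 3 fell (26 and 4 adjusted over the list alone; camera adjusted p = 1.569e-08; adjusted p = 0.957 with an estimated correlation). They included Fbln2 (3.25), the fibronectin gene Fn1 (2.86, from 22.8 to 202 FPKM with the negative-control inhibitor), the protease genes Adam12 (2.63) and Mmp2 (2.51), and Thbs1 (2.31). Of 29 genes of the TGF-β/Smad response, 20 rose and 8 fell (21 and 8 adjusted over the list alone; camera adjusted p = 6.172e-05; adjusted p = 0.957 with an estimated correlation). The feedback gene Pmepa1 rose by 3.66. Of 9 genes of the BMP/Id response, 8 rose, among them Id3 (2.47), and Id2 fell by 0.67 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00591; adjusted p = 0.957 with an estimated correlation).

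The contractile program rose in part. Acta2, the smooth muscle actin commonly used as a marker of mesenchymal transition, rose by 3.58 ± 0.13 (adjusted p = 9.202e-05), from 0.134 to 16.7, 0.113 to 10.2 and 0.158 to 11.7 FPKM. Of 17 smooth muscle and contractile genes tested, 12 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 4.523e-04; adjusted p = 0.957 with an estimated correlation). Tpm1 rose by 2.17, Cald1 by 1.58 and Cnn2 by 1.03, while Tagln and Cnn1 were at or under 0.608 and 0.507 FPKM in every library. Of 26 targets of SRF and its coactivator MRTF, 18 rose, with Fhl1 at 2.80 and Cyr61 at 1.55, and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 2.936e-05; adjusted p = 0.957 with an estimated correlation). Of 15 YAP/TAZ targets, 10 rose, with Nuak2 at 2.08 and Tgfb2 at 1.80, and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 4.523e-04; adjusted p = 0.957 with an estimated correlation). The fry test also called the matrix, Smad, BMP/Id, smooth muscle, SRF/MRTF and YAP/TAZ lists (adjusted p = 0.0205 each).

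Endothelial genes moved in both directions. Of 30 tested, 10 rose, with Sox18 at 1.83 and Nrp1 at 0.97, and 12 fell, with the nitric oxide synthase gene Nos3 at -1.23 and Gpihbp1 at -1.18 (camera adjusted p = 0.770, median -0.08, mean 0.05). The VEGF receptor gene Kdr fell by 0.80, from 62.6 to 37.2 FPKM with the negative-control inhibitor. Pecam1 and Cdh5, which encode junction proteins of endothelial cells, did not pass, at 597 and 629 FPKM and at 180 and 167 FPKM without and with TGF-β. Among 5 lymphatic genes, 2 rose, Foxc2 by 1.32 and Flt4 by 0.38, and 3 fell, with Lyve1 at -1.58 (camera adjusted p = 0.797). Of 14 mesenchymal markers, 8 rose, including Pdgfra (2.53), Ncam1 (1.83) and Itgb3 (1.53), and 4 fell (camera adjusted p = 0.139). Vim, which encodes an intermediate filament of mesenchymal cells, fell by 1.21, from 3013 to 1314 FPKM. Of 11 Notch pathway genes, 3 rose and 6 fell, with the ligand genes Dll4 at -1.81 and Dll1 at -1.66 (camera adjusted p = 0.248, fry adjusted p = 0.0205). In these 4 lists and in the TGF-β counts of those that follow, the counts adjusted over the list alone differed by at most 2 genes in a direction.

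Some cell cycle genes fell with TGF-β, as did 3249 of all 11816 genes tested. Of 41 proliferation genes, 12 fell and none rose, with Ube2c at -0.47 and E2f1 at -0.44 (camera adjusted p = 0.0282; adjusted p = 0.957 with an estimated correlation). Without the library with the miR-31 inhibitor and TGF-β, 12 fell as well. The list's median response was -0.21 with the miR-31 inhibitor (percentile 0.625 of random lists of like expression), but -0.05 with the negative control and with the miR-27 inhibitor (percentiles 50.9 and 53.6). Of 20 replication-dependent histone genes, 4 fell and 0 rose, with Hist1h1c at -0.37 (camera adjusted p = 0.348), and without the library with the miR-31 inhibitor and TGF-β 3 rose and 3 fell. Secreted factors divided, with 9 of 29 higher, such as Igf1 (2.60) and Igfbp7 (1.98), and 13 lower, such as Spp1 (-1.95) (camera adjusted p = 0.672). Of 36 NF-κB targets, 18 rose, with Cd40 at 2.98, and 8 fell, with Traf1 at -1.79 and Ccl2 at -1.26 (camera adjusted p = 0.120). Among 40 interferon-stimulated genes, 7 rose, with Zbp1 at 1.05, and 13 fell, with Ifit3 at -0.69 (camera adjusted p = 0.684). Of 25 hypoxia and glycolysis genes, 11 rose, with Ddit4 at 2.54 and Bnip3 at 1.75, and 5 fell (camera adjusted p = 0.120).

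Among 18 targets of p53, 3 rose, with Trp53inp1 at 0.73, and 6 fell, with Gdf15 at -1.55 (camera adjusted p = 0.855). MS-1 cells carry the large T antigen of SV40, which binds p53. Of 22 genes of cholesterol synthesis, 5 rose and 7 fell, with Sqle at -0.58 and Stard4 at 0.55 (camera adjusted p = 0.916, median 0.02, mean -0.02). Of 26 genes of the unfolded protein and amino acid stress responses, 10 rose, with Cebpb at 0.93, and 5 fell, with Asns at -1.16 (camera adjusted p = 0.432). Without the library with the miR-31 inhibitor and TGF-β, in which this list stood apart, 13 rose and 11 fell. Of 11 small RNA pathway genes, 2 fell, Eif2c2 by 0.50 and Drosha by 0.37 (camera adjusted p = 0.432), and without that library 2 rose and 3 fell. A value of 0 in this table need not mean absent RNA, since Eef1a1, a translation factor gene expressed in all cells, was listed at 0 in all 6 libraries. Of the 13 other housekeeping genes, 3 fell, Ywhaz by 0.34, Rplp0 by 0.18 and Rpl13a by 0.14, and 0 rose (camera adjusted p = 0.923), and without that library 1 rose and 3 fell.

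Markers of other cell types were mostly near 0. Of 12 leukocyte markers, 2 were tested: Cd68, a lysosomal protein gene, fell by 0.65 from 169 to 105 FPKM with the negative-control inhibitor, and Lyz2 rose by 0.21. Of 10 epithelial markers, only Krt18 was tested, and this keratin gene fell by 1.72, from 38.2 to 11.4 FPKM. No pancreas marker reached the filter, with all 11 at or under 0.0330 FPKM. The table held 1 of 13 mitochondrially encoded genes, mt-Nd4, which did not pass (0.09, adjusted p = 0.397).

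**Figure D2:**
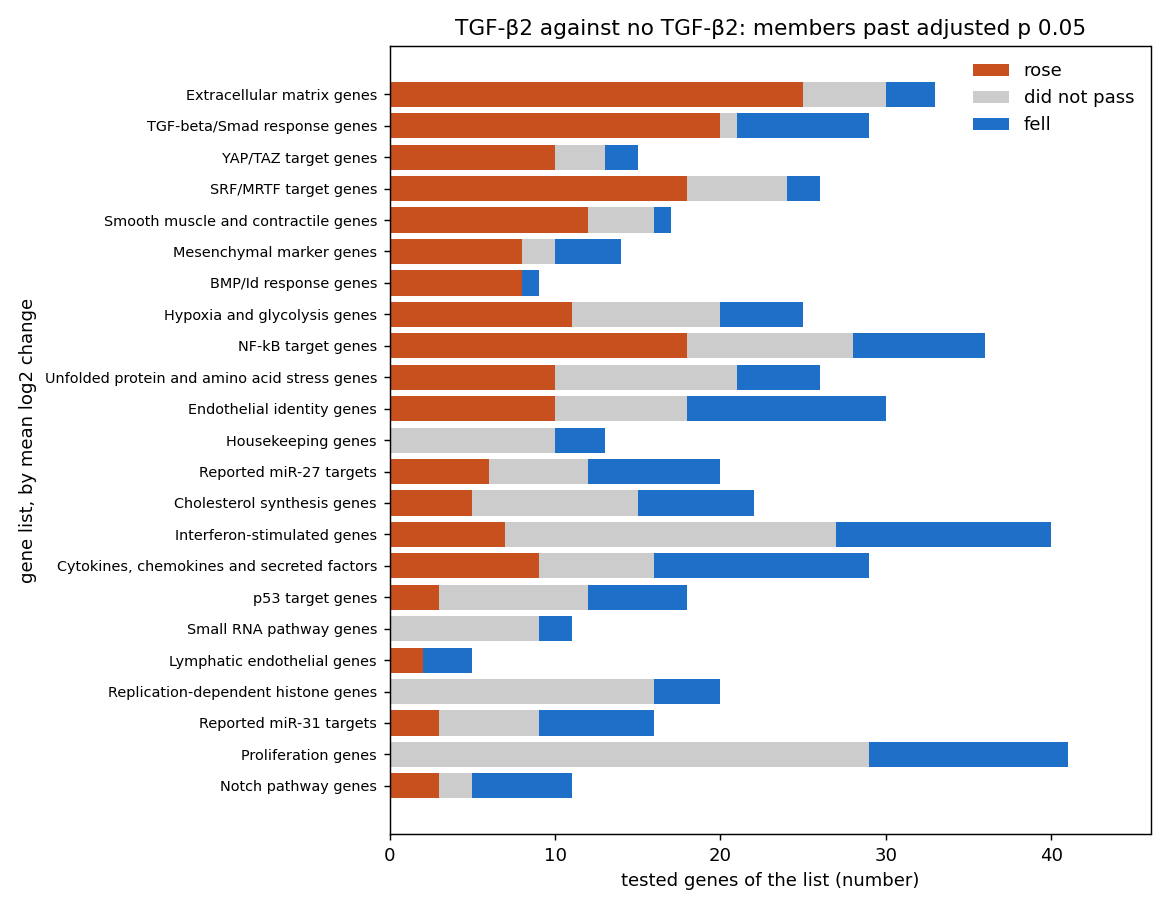
Number of tested genes (x axis) in each of 23 gene lists (y axis, ordered by mean log2 change) that rose, did not pass or fell with TGF-β at an adjusted p under 0.05. Of 33 matrix genes 25 rose, whereas of 30 endothelial identity genes 10 rose and 12 fell.

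In all, 2677 genes rose and 3249 fell with TGF-β at an adjusted p under 0.05, out of 6825 genes with an unadjusted p under 0.05. Of the genes called, 279 rose and 233 fell by at least 1 on the log2(FPKM + 1) scale, and all 5926 had the same sign in the 3 transfections. Genes that differed by at least 1 numbered 310 higher and 251 lower with the negative-control inhibitor, 313 and 287 with the miR-31 inhibitor, and 287 and 241 with the miR-27 inhibitor. The 3 responses correlated across genes, which are not independent replicates: 0.879 for the negative control and miR-31 inhibitors, 0.934 for the negative control and miR-27 inhibitors, and 0.895 for the miR-31 and miR-27 inhibitors, without names listed at 0 and short RNAs. Over all genes tested the values were 0.708, 0.783 and 0.640. The count of calls was 3566 without either negative-control library and 3917 without either miR-27 library.

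The study's EndMT secretory genes rose with TGF-β, and several rose less with the miR-31 inhibitor. Ccl17 encodes a chemokine that attracts T cells (chromosome 8, 97334353 to 97335936). It went from 0.0957 to 19.5 FPKM with the negative-control inhibitor and from 0.0742 to 16.6 with the miR-27 inhibitor. With the miR-31 inhibitor it was listed at 0 without TGF-β and at 6.83 FPKM with it, 35.0% of the negative-control level. Cx3cl1, a chemokine anchored in the membrane, reached 4.29, 2.54 and 3.98 FPKM with the negative-control, miR-31 and miR-27 inhibitors, from 0.859, 0.918 and 0.839. Il6 reached 4.46, 2.98 and 3.44 FPKM. Angptl2, a secreted angiopoietin-like factor, went from 3.23 to 7.19, 4.12 to 4.54 and 4.05 to 7.49 FPKM. Cxcl16 lay under the filter and reached 1.13, 1.10 and 1.12 FPKM. The 4 genes tested rose with TGF-β over the 3 transfections (4 adjusted over the list alone), Ccl17 by 3.74 ± 0.25 (adjusted p = 4.865e-04) and Angptl2 by 0.61 ± 0.17 (adjusted p = 0.0346).

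The miR-31 targets that the study follows fell with TGF-β and were higher with the miR-31 inhibitor. Vav3, which encodes a signalling protein, fell by 1.34 ± 0.05 (adjusted p = 9.052e-05), from 11.1 to 3.82, 12.6 to 4.64 and 11.8 to 3.76 FPKM. Stk40, which encodes a kinase-like protein reported to restrain NF-κB signalling, fell by 0.40 ± 0.11 (adjusted p = 0.0327). Its responses were -0.63 with the negative-control, -0.10 with the miR-31 and -0.46 with the miR-27 inhibitor, from 2.43, 2.79 and 2.12 FPKM without TGF-β. With TGF-β it stood at 1.21 FPKM with the negative-control inhibitor, 2.53 with the miR-31 inhibitor and 1.27 with the miR-27 inhibitor. Over both states, Stk40 was higher with the miR-31 inhibitor by 0.41 and Vav3 by 0.20, with adjusted p of 0.244 and 0.236 over all genes tested. Both passed when adjusted over the list alone, which is not independent evidence because the study chose these genes. The 3′ UTRs of Vav3 and Stk40 hold 1 and 3 sites for the miR-31 seed. The library with the miR-31 inhibitor and TGF-β also stood apart in its stress genes, with a median of that list 0.92 above the negative control, so the differences in Ccl17, Cx3cl1, Angptl2 and Stk40 come from a library that differs in more than these genes. Whether the responses differ between the inhibitors was not tested.

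**Figure D3:**
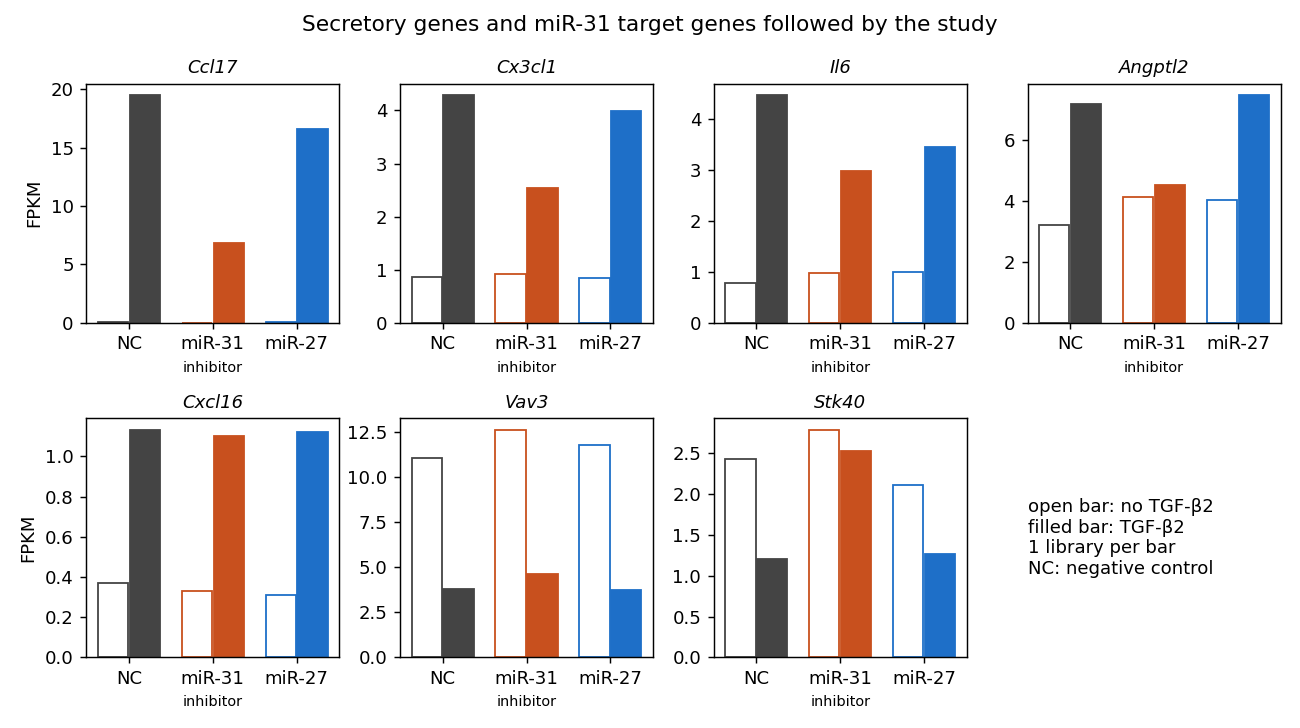
FPKM (y axis, from 0) of the 5 secretory genes and both miR-31 targets that the study follows, by inhibitor (x axis), with 1 library per bar, open without and filled with TGF-β, and NC for the negative control. Ccl17 reaches 19.5 FPKM with the negative-control inhibitor, 16.6 with the miR-27 inhibitor and 6.83 with the miR-31 inhibitor.

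With the miR-31 inhibitor, Gadd45a, Angpt2 and Kit were among the genes with the largest differences above the negative control in both TGF-β states, but none of these passed over all genes tested. Gadd45a, a growth arrest gene, was at 41.4 against 22.3 FPKM without TGF-β and at 211 against 75.2 with it. Angpt2 was at 87.7 against 48.9 and at 7.41 against 4.08 FPKM, and the receptor gene Kit was at 19.9 against 12.6 FPKM without TGF-β (0.62 and 0.66). Arrdc3 (0.66 and 0.75), Hmox1 (0.61 and 1.31), mKIAA4222 (0.66 and 0.70) and mKIAA4180 (0.62 and 0.72) were also higher, as log2 differences without and with TGF-β, and Trib3 was at 73.7 against 47.7 and at 95.3 against 11.1 FPKM. Txnip, which encodes an inhibitor of thioredoxin and of glucose uptake, was lower, at 41.9 against 79.2 and at 16.9 against 60.9 FPKM. So were Msln (-0.75 and -0.78), Sprr2b (-0.80 and -1.13), asp3 (-1.11 and -0.71), Snhg9 (-0.70 and -0.78) and Dynlt1c (-1.83 and -1.74), whose gene has close copies.

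Mapk9 and Jnk2, both names of the JNK2 kinase gene at the same place on chromosome 11 (49660253 to 49699923), were listed at 0 in both libraries with the miR-31 inhibitor. Mapk9 stood at 19.9 and 23.0 FPKM with the negative control and at 19.9 and 22.9 with the miR-27 inhibitor. They account for 2 of the 4 genes that passed, all lower and 3 of them listed at 0 with the inhibitor, beside 2135 at an unadjusted p under 0.05. The count was 1137 without the miR-31 library that lacked TGF-β, 13 without the negative-control library with TGF-β, 10 without the miR-31 library with TGF-β, and 13 with trend and robust options. The other calls, named after their values were seen, were the short RNAs Mir763, listed at 0 with the inhibitor, and Scarna3b. Scarna3b fell from 606 to 169 FPKM without TGF-β and from 671 to 190 with it (-1.83 ± 0.09, adjusted p = 0.0159), although FPKM measures such short RNAs poorly. Differences of at least 1 numbered 10 higher and 21 lower without TGF-β and 51 and 30 with it, but only 1 and 4, and 36 and 13, when names listed at 0 and the short or unnamed models were left out.

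Among the fixed lists, the stress genes had the largest shift with the miR-31 inhibitor (median 0.51, camera adjusted p = 2.632e-06; adjusted p = 0.957 with an estimated correlation). The median difference of these 26 genes was 0.12 without TGF-β and 0.92 with it. With the miR-27 inhibitor the list's median over both TGF-β states was 0.15 (camera adjusted p = 0.131), beside the 0.51 with the miR-31 inhibitor. Its median without TGF-β is not given here, so the 0.12 alone does not set the miR-31 inhibitor apart. The YAP/TAZ targets were higher (median 0.12, camera adjusted p = 0.00197; adjusted p = 0.957 with an estimated correlation), led by Gadd45a and Ankrd1. Hypoxia genes were higher too (median 0.15, camera adjusted p = 0.00337; adjusted p = 0.957 with an estimated correlation), with Ddit4 (0.74), Ndrg1 (0.60) and Vegfa (0.59). Proliferation genes were lower (median -0.13, camera adjusted p = 3.005e-05; adjusted p = 0.957 with an estimated correlation), at -0.06 without TGF-β and -0.21 with it. No member passed over all genes, and adjusted over the list alone 4 YAP/TAZ targets, 6 hypoxia genes, 0 stress genes and 0 proliferation genes passed. Adjusted over the list alone, 6 secreted factor genes were higher and 3 lower, and 3 Smad response genes higher and 1 lower. The fry test for a shift in a single direction called none of the lists for either inhibitor. Its test for changes in either direction, which does not compare a list with other genes, called 8 of 24 lists for each inhibitor, among them the hypoxia (adjusted p = 0.0295 and 0.0279) and endothelial identity lists (adjusted p = 0.0235 and 0.00575 for miR-31 and miR-27), and 23 for TGF-β.

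With the miR-27 inhibitor, Gadd45a, Arrdc3, Trib3, Txnip, Sprr2b and Msln were again among the genes named by the rule. Gadd45a was at 48.8 against 22.3 FPKM without TGF-β and at 115 against 75.2 with it, and the stress gene Ddit3 at 70.1 against 41.0 and at 39.8 against 19.6. Arrdc3 (0.85 and 0.76), the kinase gene Pim1 (0.80 and 0.72), Nupr1 (0.69 and 0.90), the cystine transporter gene Slc7a11 (0.78 and 0.63) and Trib3 (0.60 and 0.91) were higher as log2 differences without and with TGF-β. Rbm9 (0.69 and 0.88) was higher as well, and its name was listed at 0 in 1 library with the miR-31 inhibitor. Txnip was at 43.1 against 79.2 and at 28.1 against 60.9 FPKM. Also lower were the acute phase gene Saa3 (-0.61 and -1.17), Sprr2b (-0.95 and -0.55), Aldh3a1 (-0.49 and -0.55), Msln (-0.44 and -0.56), RIE2 (-0.85 and -0.53) and mKIAA1049 (-0.45 and -0.61). NCX1 (-1.45 and -3.42) shares its place with Slc8a1, which stood at 16.0 against 14.9 and at 7.75 against 7.82 FPKM. None of these passed; the 1 gene that did was Mir763, listed at 0, beside 1470 at an unadjusted p under 0.05. The count was 12 without the negative-control library with TGF-β, and 3 and 6 without the miR-27 libraries that lacked and had TGF-β.

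The lists that shifted with the miR-27 inhibitor were mostly those of the miR-31 inhibitor. Hypoxia genes were higher (median 0.15, camera adjusted p = 2.632e-06; adjusted p = 0.957 with an estimated correlation), with Adm and Vegfa at 0.60 each, and 7 passed adjusted over the list alone. YAP/TAZ targets were higher (median 0.16, camera adjusted p = 6.172e-05; adjusted p = 0.957 with an estimated correlation), with 2 passing adjusted over the list alone. Proliferation genes (median -0.08, camera adjusted p = 0.00197; adjusted p = 0.957 with an estimated correlation) and cholesterol genes (median -0.06, camera adjusted p = 0.0144; adjusted p = 0.957 with an estimated correlation) were lower, with 0 members passing adjusted over the list alone. Differences of at least 1 numbered 14 higher and 21 lower without TGF-β and 13 and 10 with it, but only 4 and 5, and 5 and 5, when names listed at 0 and the short or unnamed models were left out. The differences of both inhibitors from the negative control correlated across genes at 0.792 without TGF-β and 0.596 with it. Both use the same negative-control libraries, so part of the correlation may come from the shared controls. Simulated values linked by these alone gave 0.483 (covariance 0.0104, against 0.0210 observed without TGF-β). Equal noise in every library sets that correlation whatever the data are. The noise was the residual spread of the fit, which also holds any dependence of the TGF-β response on the inhibitor. The simulation therefore does not measure how large that part is. For pairs of differences that share no library the values were 0.322 and 0.363. All of these leave out names listed at 0 and short RNAs, and over all genes tested the pairs with a shared control gave 0.584 and 0.361 and those without gave 0.231 and 0.242.

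Between the inhibitors, stress genes were higher with the miR-31 inhibitor (median 0.28, camera adjusted p = 9.976e-08; adjusted p = 0.957 with an estimated correlation). Proliferation genes (median -0.05, camera adjusted p = 0.0255; adjusted p = 0.957 with an estimated correlation) and reported miR-27 targets (median -0.07, camera adjusted p = 0.0352; adjusted p = 0.957 with an estimated correlation) were lower with it. The stress difference rests mainly on the library with the miR-31 inhibitor and TGF-β. Against the negative control, the list's median with the miR-31 inhibitor was 0.12 without TGF-β and 0.92 with it. Over both states it was 0.51 with the miR-31 inhibitor and 0.15 with the miR-27 inhibitor. The estimated correlation between genes of this list was 0.85. Only Mapk9 and Jnk2 passed, both listed at 0 with the miR-31 inhibitor, beside 403 genes at an unadjusted p under 0.05. The count was 208 without the miR-31 library that lacked TGF-β, 7 without the miR-31 library with TGF-β, and 4 and 6 without the miR-27 libraries that lacked and had TGF-β.

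As lists, the reported targets of the inhibited microRNAs had median differences under 0.1. The genes of the microRNAs themselves, Mir31, Mir27a and Mir27b, were listed at 0 in all 6 libraries, so the table holds no measure of the inhibition. Of 16 reported miR-31 targets, 0 passed with the miR-31 inhibitor (median 0.07, camera adjusted p = 0.368, 0 adjusted over the list alone). With TGF-β, 3 rose, with Fat4 at 1.69, and 7 fell, with the receptor signalling inhibitor Spry4 at -2.04 (camera adjusted p = 0.593). Of 20 reported miR-27 targets, 0 passed with the miR-27 inhibitor (median 0.08, camera adjusted p = 0.127, 1 adjusted over the list alone), with the adipocyte regulator Pparg at 0.37. With TGF-β, 6 of them rose, with Cyp1b1 at 1.87 and Abca1 at 1.25, and 8 fell, with Plxnd1 at -1.01 (camera adjusted p = 0.916).

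Sites for the seeds were searched in the 3′ UTRs of 10478 tested genes. The miR-31 site TCTTGCC occurred in 1379 genes, whose median difference with the miR-31 inhibitor was 0.019, against 0.020 for random genes of like expression and 3′ UTR length (percentile 31.9). It ranked 73 among the 140 arrangements of its bases. The miR-27 site ACTGTGA occurred in 1847 genes, whose median difference with the miR-27 inhibitor was 0.018 against 0.012 (percentile 99.9), and ranked 60 among 630 arrangements. Camera gave an adjusted p of 0.711 for both sets.

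The library with the miR-31 inhibitor and TGF-β held high levels of genes that respond to unfolded proteins and to amino acid shortage. Ddit3, which encodes a transcription factor induced by endoplasmic reticulum stress, was at 298 FPKM there, against 19.6 with the negative control and 39.8 with the miR-27 inhibitor. Herpud1, a factor in the disposal of misfolded proteins, was at 218 against 21.5 and 31.2 FPKM. Chac1, which degrades glutathione, was at 109 against 7.06 and 16.4, Trib3 at 95.3 against 11.1 and 21.7, and the transcription factor gene Atf3 at 88.8 against 25.1 and 22.0. Without TGF-β the 3 libraries were closer, with Ddit3 at 59.2, 41.0 and 70.1 FPKM with the miR-31, negative-control and miR-27 inhibitors. The heat shock gene Hspa1b and the stress gene Sesn2 had TGF-β responses 1.61 and 1.58 above both others. Of the 26 stress genes, 24 had a higher response with the miR-31 inhibitor than in both other transfections, 10 of them by at least 1. The median gap of 0.60 exceeded those of all random lists of like expression. The random lists hold unrelated genes, whereas the estimated correlation within this list was 0.85, so that rank overstates how unusual the gap is. In the same library the proliferation genes (median gap -0.11, 33 of 41 lower) and histone genes (-0.21, 18 of 20 lower) had lower responses than in both other transfections. Lower responses were not confined to these lists, and also held for mesenchymal markers (-0.12, 11 of 14 lower) and matrix genes (-0.06, 28 of 33 lower).

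Genes whose response stood at least 1 apart from both others numbered 34 above and 24 below with the miR-31 inhibitor, 15 and 8 with the miR-27 inhibitor, and 9 and 13 with the negative control. Without names listed at 0 and the short or unnamed models, the counts were 22 and 4, 5 and 2, and 3 and 2. The largest gaps below with the miR-31 inhibitor were Rbbp7, Nolc1, Rbfox2, Msl1, Txlng, Casc3 and Rbm9, all listed at 0 in the library with TGF-β, where Rbbp7 stood at 187 and 173 FPKM in the other transfections, and Hexdc (-2.55). Deltex3 (2.56 above with the miR-31 inhibitor) was listed at 0 in 2 libraries. With the miR-27 inhibitor, Lars2 (3.03), Commd4 (1.42) and hnRNP_A2/B1 (1.30) stood above. Hnrnpc was listed at 0 without TGF-β. R3hdm2 (-3.56) and Smyd2 (-1.57) stood below, as did Deltex3, listed at 0 with TGF-β, and IL15ra, the next lowest, was under 1 apart (-0.78). These gaps were not tested.

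**Figure D4:**
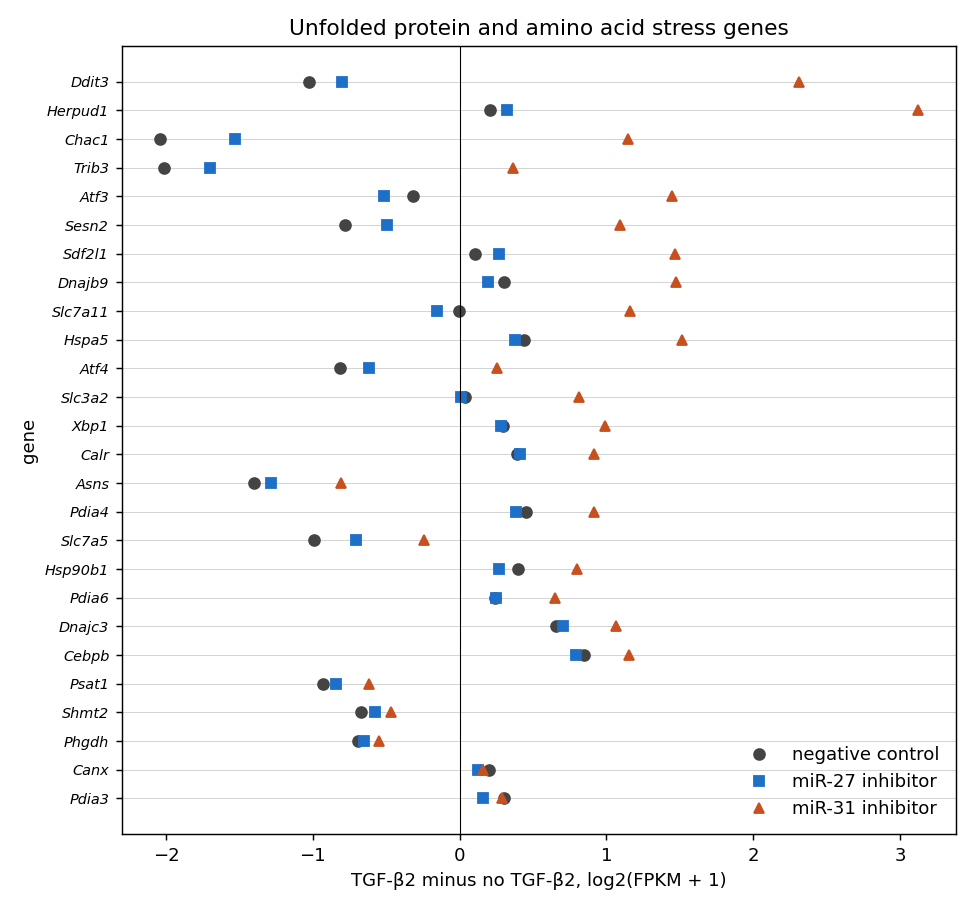
TGF-β response, as the difference in log2(FPKM + 1) between the libraries with and without TGF-β (x axis), of the 26 stress genes (y axis), with 1 point per transfection. The response with the miR-31 inhibitor (triangles) lies above both others for 24 genes, and for Ddit3 it is 2.31 against -1.03 with the negative control and -0.80 with the miR-27 inhibitor.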

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

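Chosen only after the result was seen were the tests of a direct effect of the miR-31 inhibitor, of a site in each stress gene, of a stressed culture, of the genes shared by both inhibitors and of the names listed at 0. The differences between transfections given here were not tested.

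Some genes drew attention because their TGF-β response went in the opposite direction with 1 inhibitor from that in both other transfections. With the miR-31 inhibitor, as log2 responses beside those with the negative control and the miR-27 inhibitor, they were Ddit3 at 2.31 (-1.03 and -0.80), Chac1 at 1.15 (-2.04 and -1.53), Trib3 at 0.37 (-2.01 and -1.70), Atf3 at 1.44 (-0.32 and -0.52), Hspa1b at 1.53 (-0.35 and -0.07), Sesn2 at 1.09 (-0.78 and -0.49) and Hexdc at -2.50 (2.0 and 0.05). With the miR-27 inhibitor, beside the negative control and the miR-31 inhibitor, they were Lars2 at 1.93 (-1.09 and -1.63), Commd4 at 0.0356 (-1.39 and -1.74), hnRNP_A2/B1 at 1.18 (-0.26 and -0.12) and R3hdm2 at -3.09 (0.47 and 1.27).

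The first pattern is the rise of stress genes in the library with the miR-31 inhibitor and TGF-β. Library scaling as the cause is argued against by quantile normalization, after which the median gap was 110% of the deposited one (0.66 against 0.60). A 7-base miR-31 site in each gene is argued against by the 23 of 26 list members without such a site in an annotated 3′ UTR. Among the 18 genes that stood apart and have a 3′ UTR, 0% held a site (Fisher's exact test, 2-sided, p = 0.156), but only 52.9% of the 34 genes could be searched, so this decides nothing. Without TGF-β the median difference from the negative control was 13.0% of that with it, which restates how the pattern was found, so an effect of the miR-31 inhibitor by itself, a joint effect with TGF-β and a stressed culture in 1 well cannot be told apart with 1 library of this condition.

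The second pattern is that the differences of both inhibitors from the negative control correlated across genes. Counting and estimation error of the negative-control libraries would leave no correlation between differences that share no library, and their mean correlation across all genes tested was 0.236. A shared shift of the negative-control cultures and a real effect common to both inhibitors cannot be told apart, with 1 negative-control library per TGF-β state.

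The third pattern is that 41 tested names were listed at 0 in some libraries and at 1 FPKM or more in others of the same TGF-β state. If a locus had not been estimated in such a library, the other names at that place would be at 0 too. That held for 31.25% of 96 entries, which argues against this as the whole cause. An entry is another name at the place, counted again for each name listed at 0 and each library, so entries are not independent. For the names not skipped by the rule for short or unnamed models it held for 63.6% of 22 entries. The exceptions lay at the places of Deltex3, BC043476 and mKIAA3005. For Casc3, Msl1, Rbbp7, Txlng, Rbfox2, Rbm9, Mapk9 and Jnk2, all other names at the place were at 0 in the same library. A locus left without an estimate would give this, but a real loss cannot be told apart from it. No biological explanation was tested.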

How the results depend on the processing

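Leaving out names listed at 0 or short RNAs, and recounting list members, were tests chosen only after the result was seen. No paired analysis was possible beyond the pairing by inhibitor that the fit holds, because the groups share fewer than 2 replicate numbers. With all 6 libraries, 5926 genes passed for TGF-β, and the 10 ways of splitting the libraries into 3 and 3 are too few for a share under 0.05 (1 split, the real one, reached 5926; the highest other gave 7). Under the alternatives that kept all libraries the TGF-β count lay between 4719 (mean of 5 FPKM, where all 4498 of the calls measured were kept) and 6156 (trend and robust options), with 5450 with no inhibitor block. With no filter, 4688 of the 5926 were kept. All kept their sign where measured, except 1 with quantile normalization (5925). A pseudocount of 0.1 gave 54 genes for the miR-31 inhibitor without TGF-β and 34 standing apart with the negative control. With no filter, 0 genes passed for miR-31, for miR-27 and between them. At a mean of 5 FPKM, 1 passed between the inhibitors, with 20 for miR-31 without TGF-β and 14 standing apart with the negative control, where fewer genes were tested. Without names listed at 0, 1 gene passed for miR-31, 0 for miR-27 and 0 between them; 11 differed by 1 for miR-31 without TGF-β, 16 and 13 for miR-27 without and with it, and 35, 12 and 9 stood apart with the miR-31, miR-27 and negative-control inhibitors. Without short RNAs, 2 passed for miR-31 and 0 for miR-27, with 19 for miR-31 without TGF-β and 15 standing apart with miR-27. Trend and robust options gave 13 for miR-31. The 18 list calls became 0 with an estimated correlation and 8 with fry. Except where names or genes were left out, the cause was not tested.

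Leaving out 1 library at a time, the TGF-β count ranged from 3566 (either negative-control library) to 6087 (either miR-31 library), with 3917 without either miR-27 library. The count for miR-31 ranged from 3 to 1137, the latter without the miR-31 library that lacked TGF-β, with 13 without the negative-control library with TGF-β and 10 without the miR-31 library with it. For miR-27 it ranged from 1 to 12 (without the negative-control library with TGF-β), with 3 and 6 without the miR-27 libraries that lacked and had TGF-β. Between the inhibitors it ranged from 2 to 208 (without the miR-31 library that lacked TGF-β), with 7 without the miR-31 library with TGF-β and 4 and 6 without those of miR-27. The partner of a library left out then sets its own mean and is assumed to vary like the rest; the cause was not tested. Of the values of named genes, 25 moved and 215 did not. Absolute depth is unknown, so no limit from counts can be given.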

Other observations

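All values here were chosen after the tests of the report were seen, and the percentiles are of random lists of like expression. Those lists hold unrelated genes, so a list whose genes move together ranks as more extreme than it is.

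Interferon-stimulated genes, which cells switch on against viruses and foreign RNA, did not pass as a list with the miR-27 inhibitor over both TGF-β states (camera adjusted p = 0.594; adjusted p = 0.957 with an estimated correlation; fry adjusted p = 0.844 in a single direction and 0.0317 in either), and 0 of 40 members passed. The list's median over both states was 0.04 with either inhibitor (camera adjusted p = 0.836 for miR-31), so that shift was not particular to the miR-27 inhibitor. By single libraries, with the miR-27 inhibitor 29 were higher than with the negative control without TGF-β (median 0.09, percentile 99.97), and 19 with TGF-β (median -0.01). Their TGF-β response was lower than in both other transfections for 27 of 40 (median gap -0.08, below all random lists). The histone genes went the other way, with 15 of 20 responses above both others (median gap 0.14). The reported miR-31 and miR-27 targets had responses with the miR-31 inhibitor below those with the negative control in 11 of 16 and 14 of 20 genes (medians -0.16 and -0.12). None of these differences between responses was tested.

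Mir715, listed on chromosome 17 at 39981081 to 39981190, had by far the highest values of the genes named here, at 588658, 458638 and 344340 FPKM without TGF-β with the negative-control, miR-31 and miR-27 inhibitors and 203587, 214662 and 200599 with it (-1.14, adjusted p = 0.00333). A model of this length is measured poorly by FPKM, so neither these values nor the fall is taken as a measure of a microRNA.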
